A study of Mus musculus with 4 samples.

How the data were processed

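Livers of male mouse offspring were dissociated and sequenced as single cells with the 10x Genomics 3′ droplet method. Per the labels' protocols, livers of the fetuses of 3 pregnant mice or of 3 adult animals were pooled for each library, digested with collagenases, hyaluronidase and DNase, spun at low speed and treated with a red cell lysis buffer, and adult livers were first perfused through the portal vein. There is 1 library for each of 4 groups: fetal offspring at embryonic day 18.5 and adult offspring at 8 weeks, from control mothers (Ctrl) or from mothers with hyperglycemia in pregnancy (IHG, intrauterine hyperglycemia). The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, written by Cell Ranger 5.0.0 per the file headers. The genome build mm10 and the tools Cell Ranger and Seurat are named in the submitters' processing notes, which assign Seurat no step. All 4 count tables hold the same 32285 genes and only barcodes with at least 500 UMIs. No cell annotation was used.

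Cells were kept with at least 300 genes and at most 25% mitochondrial UMIs. Doublets were scored per library with Scrublet in scanpy 1.11.5 and removed at its own threshold in the fetal libraries (178 in Ctrl, 246 in IHG). That threshold marked 0.0385% and 0.221% of the adult barcodes, under the preset minimum of 0.5%, so barcodes with a score above the 95th percentile were removed there (258 of 5195 in Ctrl, 299 of 6786 in IHG), and barcodes tied at that score were kept. This left 7523 fetal Ctrl, 7946 fetal IHG, 4937 adult Ctrl and 6487 adult IHG cells. The 2 libraries of an age were clustered together without batch integration, from the log of counts per 10000, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9). Mitochondrial and ribosomal genes were left out of the variable genes, as were genes of the response lists unless they were cell type markers. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were also used.

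Clusters were named "X-like" from marker lists for 19 cell classes. A cluster stayed unnamed with fewer than 3 detected markers, with more markers of another class among its 10 leading genes, or with shallow cells and no own marker among those genes. Ties also left a cluster unnamed. In a tie another class had as many markers among those genes, but not none, and the 2 best scores lay within a set margin. The margin was set after the clusters had been seen. It left fetal cluster 19 unnamed (309 Ctrl and 44 IHG cells, 4.11% and 0.554% of cells, with B cells as its best-scoring class, tied with plasma cells), and fetal cluster 21 (57 and 174 cells, 0.758% and 2.19%, mast cell and stem cell markers tied). Fetal clusters 13, 15 and 16 were unnamed under the other rules.

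UMIs were summed per library and class and scaled by the class total (CPM). Ratios are IHG over Ctrl on the log2 scale. With 1 library per group there is no test and no replicate check, and cells are not replicates. Shares carry exact Clopper-Pearson 95% intervals, ratios of genes and of shares carry exact conditional Poisson 95% intervals, and list medians carry 95% intervals from 1000 Poisson resamples of the counts. All of these cover counting error only, and not differences between cells, animals, dissociations or captures. Each list's value is the median log2 ratio over its members with at least 20 UMIs over both libraries, with 0.5 added to each count, and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Members that mark the class itself were left out. For a gene with 0 UMIs in 1 library the bound was computed at a floor of 3 counts per class sum. Gene positions come from GENCODE M21 on mm10, in which all 304 of the named gene IDs were found.

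The groups, filters, markers, 29 gene lists, the classes each list was to be read in and the rule for named genes were chosen before the data were examined. That rule allows every measured positive acute-phase gene in hepatocyte-like cells, up to 4 members of each list with at least 20 CPM in 1 library, and the 5 highest and 5 lowest genes, with at least 100 CPM in 1 library and at least 50 UMIs, in hepatocyte-like cells, macrophage-like cells and the largest other class. Technical genes, immunoglobulin and T cell receptor genes and markers of the class were left out of that ranking. Some genes that the rule allows are not reported here. Every list was computed in every class, which gave 574 readings, 152 of them fixed beforehand and 422 not. The 68 readings described, and which of the allowed genes serve as examples, were picked after the values had been seen. The positive and negative acute-phase lists in adult cholangiocyte-like cells and the interferon list in stellate/fibroblast-like cells are among the 422.

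The interval and list steps were tested on simulated counts drawn from the real class means, with 200 genes altered by known folds. In fetal hepatocyte-like cells (5882 genes) the interval excluded equality for 32.8% of genes altered 1.5-fold, 71.6% at 2-fold and 93.9% at 4-fold. The percentages were 67.2%, 70.1% and 95.5% in fetal neutrophil-like cells (9685 genes), and 65.7%, 83.6% and 93.9% in adult B-like cells (9636 genes). Intervals of unaltered genes held the true value in 96.4%, 95.9% and 95.7% of cases in the same order. The simulated counts were Poisson sums, the model that the intervals assume, with no variation between cells. They check the calculation and do not show how often the intervals hold for real class sums.

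Alternative settings chosen beforehand were median-of-ratios scaling, scaling without mitochondrial, ribosomal and haemoglobin genes, equal weight for every cell, list members with at least 1 or at least 100 UMIs, cells thinned to 1000 UMIs, mitochondrial maxima of 10% and 50%, minima of 500 and 200 genes, doublets kept, clustering resolutions of 0.5 and 2.0, and each library clustered by itself. Added after the data had been seen were hepatocyte-like cells without those of over 10% haemoglobin UMIs, the same hepatocyte-like cells thinned to 1000 UMIs, and shares over cells outside erythroid-like and unnamed clusters. Near-identical gene copies (Saa1 and Saa2, the alpha-globin pair, histone cluster and major urinary protein genes) cannot be separated with certainty by 3′ counts, and their single values are uncertain.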

Results

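Single-cell RNA profiles of the liver were collected from male mouse offspring of control mothers (Ctrl) and of mothers with hyperglycemia in pregnancy (IHG), as late-gestation fetuses and as adults at 8 weeks. The series design asks about inflammatory traits of the liver, and its title names the acute-phase response, the set of plasma proteins whose synthesis by hepatocytes shifts in inflammation. There was 1 library per group, a pool from the litters of 3 pregnant mice (fetal) or from 3 adult animals. The fetal Ctrl library held 8500 barcodes and 77874423 UMIs, with a median of 6645 UMIs per barcode, and the fetal IHG library 8739 barcodes and 105382968 UMIs, with a median of 9116. The adult Ctrl library held 5245 barcodes and 17987173 UMIs, with a median of 2558, and the adult IHG library 6851 barcodes and 19366065 UMIs, with a median of 2235. The fetal Ctrl library also had more cells rich in mitochondrial RNA (95th percentile 23.8% of UMIs, against 6.43% in fetal IHG) and more haemoglobin RNA (35.4% of UMIs against 20.4%). In the adult libraries haemoglobin made up 0.000256% and 0.0110% of UMIs.

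The sex list (Xist and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty) had 4 measured members, with a median log2 ratio of 0.52 in the fetal and -0.06 in the adult libraries. Xist had 1, 5, 3 and 0 UMIs in the fetal Ctrl, fetal IHG, adult Ctrl and adult IHG libraries. All intervals given cover counting error only, and no difference between libraries has a replicate check.

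The first comparison asks how the cell makeup of the fetal liver suspension differed between mothers. Neutrophil-like cells, a class that spans several clusters described below, made up 26.2% of IHG cells (2079 of 7946) and 13.1% of Ctrl cells (983 of 7523). Their log2 ratio was 1.00 (95% interval 0.89 to 1.11). B-like cells made up 10.7% of IHG cells (847) and 24.7% of Ctrl cells (1858), a log2 ratio of -1.21 (-1.33 to -1.09). Macrophage-like cells, which in the fetal liver surround and clear the nuclei of maturing red cells, were 4.43% of IHG cells (352) and 0.0798% of Ctrl cells (6), a log2 ratio of 5.80 (4.66 to 7.25). Most of these IHG cells were shallow, with 258 in cluster 20 (median 1025 UMIs) and 94 in cluster 27 (median 11172 UMIs). With cells thinned to 1000 UMIs and shallower cells left out, 222 IHG and 4 Ctrl cells remained in the class, a log2 ratio of 5.74. Hepatocyte-like cells, the source of most plasma proteins, were 1.38% (110) and 1.48% (111), a log2 ratio of -0.09 (-0.49 to 0.30).

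Among the other fetal classes, myeloid progenitor-like cells were 6.93% of IHG and 1.66% of Ctrl cells (log2 ratio 2.06), megakaryocyte-like cells 1.80% and 0.239% (2.91), endothelial-like cells 1.77% and 0.558% (1.67, 1.16 to 2.20), monocyte-like cells 4.13% and 2.78% (0.57) and plasmacytoid dendritic-like cells 1.18% and 0.678% (0.80). Erythroid-like cells were 29.2% of IHG and 40% of Ctrl cells (-0.46), and NK-like cells 0.579% and 0.877% (-0.60). Stellate/fibroblast-like cells were 0.289% and 0.226% (0.36), and unnamed clusters held 11.5% and 13.7%. Over cells outside erythroid-like and unnamed clusters, a denominator chosen after seeing the data, neutrophil-like cells were 44.1% and 28.2% (0.65). The NK-like share was higher in the IHG library when cells were thinned (0.27), with a mitochondrial maximum of 50% (0.26) or with at least 500 genes (0.20). The plasmacytoid share was lower in the IHG library when each library was clustered by itself (-0.26), and it had no value in 5 of the 9 settings that regrouped the cells. Dissociation, red cell lysis and the depth gap between the libraries can all set shares. Macrophage-like clusters 20 and 27 and neutrophil-like clusters 8 and 10 came over 90% from the IHG library, so each may be a feature of that library.

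**Figure D1:**
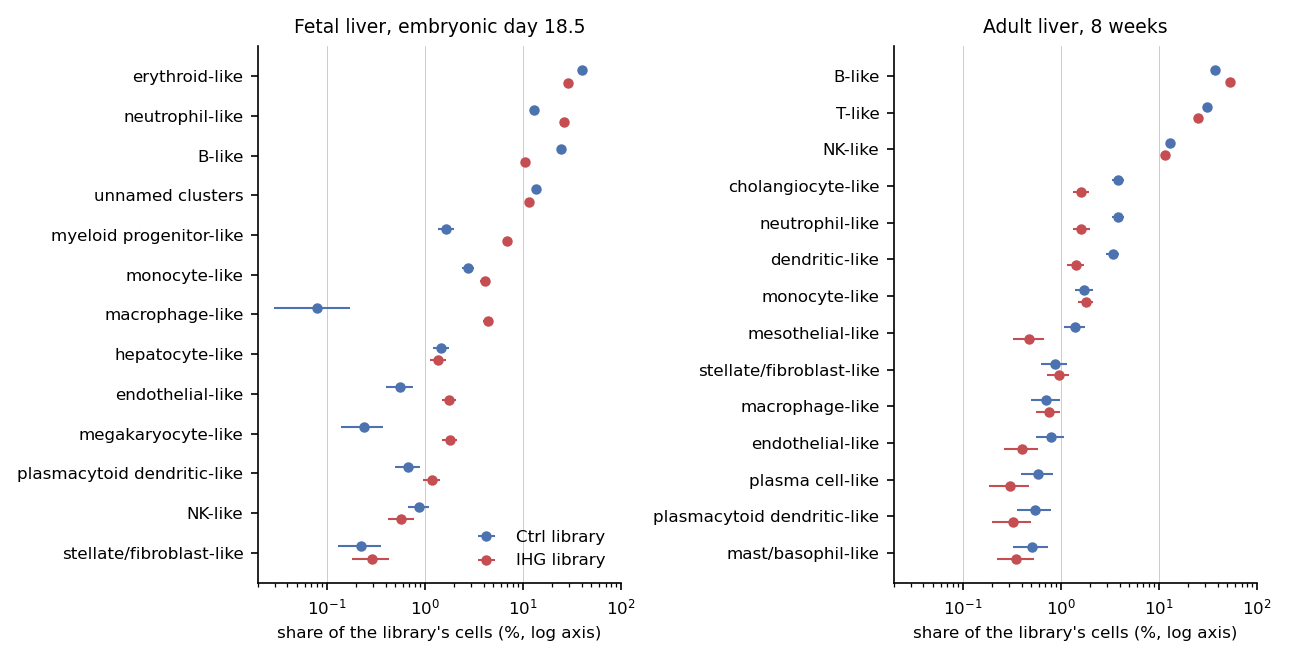
Share of each library's cells (%, log axis) in each class in fetal (left) and adult (right) liver, in Ctrl (blue) and IHG (red) libraries. Bars are exact 95% intervals for counting error, with 1 library per point, and the widest gap is that of fetal macrophage-like cells (0.0798% against 4.43%).

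The second comparison asks whether fetal hepatocyte-like cells differed in acute-phase RNA. Summed over all of these cells, 17 of 21 measured positive acute-phase genes, whose products increase in plasma during inflammation, were higher in the IHG library, with a median log2 ratio of 0.64 (0.53 to 0.79), or 1.56-fold, at percentile 99.98 of matched random lists. Haptoglobin (Hp), which binds free haemoglobin, had 797 UMIs in Ctrl and 2416 in IHG (log2 ratio 1.22, 1.10 to 1.33). The fibrinogen chains Fgb (1.08) and Fgg (1.05), the haem carrier Hpx (1.01) and Lrg1 (18 and 74 UMIs, 1.66) were also higher. Hepcidin (Hamp), the hormone that restrains iron export, was lower in the IHG library, with 733 and 338 UMIs (-1.50, -1.69 to -1.31), as was the serum amyloid gene Saa3 (57 and 49 UMIs, -0.60).

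Cells rich in haemoglobin RNA took part in this difference. In Ctrl, 21 of 111 hepatocyte-like cells had over 10% haemoglobin UMIs and held 39.4% of the class's UMIs, and in IHG 8 of 110 held 5.14%. Haemoglobin was 14.8% of class UMIs in Ctrl and 1.82% in IHG, and the haemoglobin list had a median log2 ratio of -3.06. Without those cells, a choice made after seeing the data, 12 of 21 positive acute-phase genes were higher in IHG, with a median log2 ratio of 0.18 (0.06 to 0.36), or at percentile 95.3. Hp was then at 0.80, Fgb at 0.53, Lrg1 at 1.44 and Hamp at -2.17. C3, the central complement protein, was at 0.17 over all cells and at -0.33 without them, and it was also below 0 under median-of-ratios scaling (-0.03) and without technical genes (-0.06). In the paragraphs on gene lists the value without haemoglobin-rich cells follows that over all hepatocyte-like cells. The median over all measured genes of the class was 0.19 and then 0.12, and list values are to be read against it.

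Negative acute-phase genes, plasma proteins whose synthesis is lowered in inflammation, were higher in the IHG library to a like extent, at 0.69 (7 of 8 genes) and 0.28 (5 of 8). Apoa1, the main protein of high-density lipoprotein, was at 1.25 and 0.71, and transferrin (Trf) at 1.01 and 0.55. IL-6 and STAT3 signalling genes, which drive acute-phase transcription, were at 0.71 (12 of 14 higher) and 0.32 (10 of 14, -0.02 to 0.85). Of these, the feedback inhibitor Socs3 had 24 UMIs in Ctrl and 95 in IHG (1.60 and 1.46), and the receptor chain Il6st had 3 and 26 (2.73, 1.03 to 5.10, and 1.91). Coagulation genes were at 0.61 (16 of 16) and 0.06 (10 of 16), with kininogen Kng1 at 1.02 and 0.50. Complement genes were at 0.33 (10 of 15) over all cells but at -0.31 (5 of 15) without haemoglobin-rich cells.

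**Figure D2:**
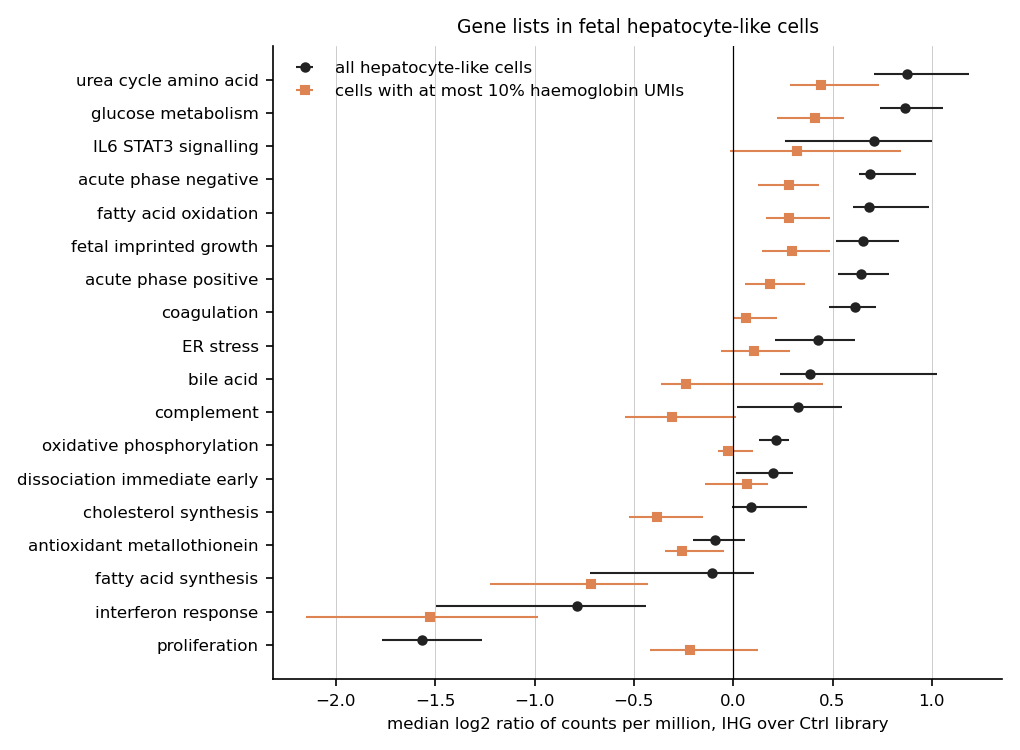
Median log2 ratio (IHG over Ctrl library) of each gene list in fetal hepatocyte-like cells, over all cells (black circles) and without cells of over 10% haemoglobin UMIs (orange squares). Bars are 95% intervals for counting error, and the positive acute-phase list lies at 0.64 and 0.18.

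Metabolic genes of the fetal hepatocyte-like cells went in both directions. Glucose metabolism genes were higher in the IHG library at 0.86 (14 of 16) and 0.41 (14 of 16, 0.22 to 0.56), led by Igfbp1, an insulin-repressed binding protein for insulin-like growth factors (513 and 2231 UMIs, 1.74 and 1.21), and Irs2, an adaptor of the insulin receptor (8 and 48 UMIs, 2.20 and 1.84). Igf1 went the other way, with 23 UMIs in Ctrl and 3 in IHG (-3.32, -5.70 to -1.60, and -3.90, -6.29 to -2.17). Urea cycle and amino acid genes were at 0.87 (10 of 10) and 0.44 (7 of 10), with the carbamoyl phosphate synthase Cps1 at 1.49 and 1.00. Fatty acid oxidation genes were at 0.68 (18 of 19) and 0.28 (14 of 18), with the omega-hydroxylase Cyp4a10 at 3.46 (6 and 86 UMIs) and 3.07. Fatty acid synthesis genes were lower, at -0.11 (7 of 9 lower, -0.72 to 0.11) and -0.72 (8 of 9, -1.23 to -0.43). Fasn, the fatty acid synthase, had 56 and 24 UMIs (-1.61 and -2.12), and the desaturase Scd1 55 and 27 (-1.41 and -1.95). Cholesterol synthesis genes were at 0.09 (13 of 18 higher) over all cells, at -0.11 under median-of-ratios scaling, at -0.14 without technical genes and at -0.39 (15 of 18 lower) without haemoglobin-rich cells. Dhcr7, its last step, was at -1.23 and -1.75. Bile acid genes were at 0.39 (9 of 9 higher) and -0.24 (4 of 9 higher), with the bile acid importer Slc10a1 at 1.11 and 0.55.

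Fetal and imprinted growth genes were at 0.65 (7 of 8 higher) and 0.29 (6 of 8), with Dlk1 at 1.11 and 0.54. ER stress genes were at 0.43 (10 of 13) and 0.11 (7 of 12), and antioxidant and metallothionein genes at -0.09 (4 of 10, and 0.15 with thinned cells) and -0.26 (3 of 10). Gpx1, a glutathione peroxidase abundant in red cells, was at -1.65 and -0.25. Proliferation genes were lower in all 19 measured members over all cells (-1.57), and in 9 of 16 without haemoglobin-rich cells (-0.22). Interferon response genes were at -0.79 (11 of 12 lower) and -1.53 (11 of 11 lower, -2.15 to -0.98), with Isg15, a ubiquitin-like antiviral protein, at 261 and 55 UMIs (-2.63 and -3.06). Isg15 is also a leading gene of erythroid-like cluster 4, and the haemoglobin list was still at -1.10 (-1.17 to -1.04) without haemoglobin-rich cells. Oxidative phosphorylation genes were at 0.21 over all cells and at -0.03 without haemoglobin-rich cells, and at -0.02 without technical genes. Immediate-early genes, which dissociation itself can induce, were at 0.20 and 0.07, and at -0.0007 under median-of-ratios scaling and -0.03 without technical genes.

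Genes of fetal hepatocyte-like cells were also ranked by size, among those with at least 100 CPM in 1 library and at least 50 UMIs. The 5 highest in the IHG library were Elane (5.14 and, without haemoglobin-rich cells, 4.47), Chil3 (3.68 and 4.32), Igfbp1, the translation inhibitor Eif4ebp3 (1.62 and 1.15) and Igfbp2 (1.58 and 0.995). A single cell gave 80.9% of Elane and 67.8% of Chil3 UMIs. The lowest included Ccl4 (-4.59 and -5.50, with 67.4% of UMIs from 1 cell), the antiviral gene Rsad2 (-3.21 and -2.03), which is also a leading gene of erythroid-like cluster 0, and the histone gene Hist1h2ap (-2.72 and -1.63). On mm10, Hp lies on chromosome 8 (109575128 to 109579172), Fgb on chromosome 3 (83040141 to 83049863), Hamp on chromosome 7 (30942368 to 30944032), Igfbp1 on chromosome 11 (7197782 to 7202546) and Fasn on chromosome 11 (120805846 to 120824547), and all are protein-coding genes.

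The third comparison asks about inflammatory genes in fetal immune and vessel cells. In neutrophil-like cells the inflammatory list, targets of NF-kB such as cytokines and their feedback regulators, was lower in the IHG library in 17 of 21 members, with a median of -0.83 (-0.94 to -0.79), or at percentile 0 of matched random lists. Nfkbiz, an NF-kB cofactor, had 2241 UMIs in Ctrl and 1232 in IHG (-2.03), the deubiquitinase Tnfaip3 304 and 238 (-1.52), the NF-kB subunit Nfkb2 180 and 152 (-1.41) and the inflammasome sensor Nlrp3 641 and 578 (-1.32). Granule protein genes were higher in IHG in 5 of 6 members, with a median of 1.05 (0.72 to 1.45), among them neutrophil elastase (Elane, 1.86) and Prtn3 (1.18). Neutrophil markers such as Ltf and Ngp were left out of this list here, and Elane and Prtn3 also mark myeloid progenitor-like cells. The granule list was higher in erythroid-like cells too, so RNA of other cells is not separated from this value. Proliferation genes were higher in 19 of 19 members (0.49). Interferon genes were at 0.15 (13 of 22 higher) and at -0.12 under median-of-ratios scaling, with Cxcl10 at -1.92 and Irf7 at 0.82. Immediate-early genes were at -0.05 (-0.20 to 0.04), with Fosb at -4.27.

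Different clusters held most neutrophil-like cells of the libraries. In Ctrl, 604 of 983 cells were in cluster 7, and in IHG 629 of 2079 were in cluster 8, 558 in cluster 10 and 498 in cluster 5. Clusters 5 and 10, with 208 and 48 Ctrl cells, had the granule genes Camp, Ltf and Ngp among their leading genes. Cluster 5 was also led by Fcnb and Cebpe, which mark myeloid progenitor-like cells too. The stage of maturation is therefore not separated from the share or the list values of the class. Within clusters the inflammatory list was at -1.05 (-1.30 to -0.79) in cluster 5, -1.07 (-1.15 to -0.90) in cluster 17, -0.31 (-0.57 to -0.07) in cluster 8, 0.47 (-0.25 to 0.88) in cluster 10 and 0.23 (-0.05 to 0.44) in cluster 7. Free RNA in the same class also differed, with the haemoglobin list at -1.64 and the hepatocyte list at 0.77 (Alb 1.60). The median over all genes of the class was 0.26.

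**Figure D3:**
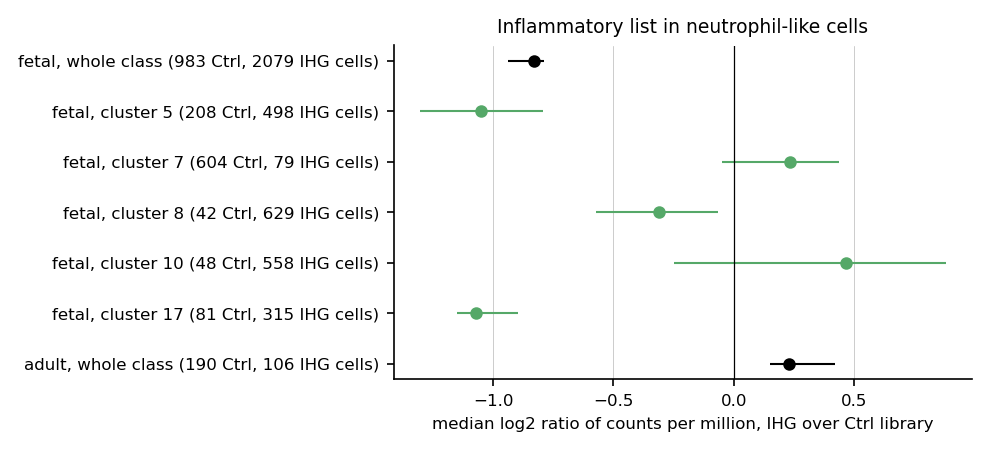
Median log2 ratio (IHG over Ctrl library) of the inflammatory list in neutrophil-like cells, for the whole class at each age (black) and each fetal cluster (green), with cell numbers on the axis. Bars are 95% intervals for counting error, and clusters 5 and 17 lie at -1.05 and -1.07 while cluster 7 lies at 0.23.

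Fetal monocyte-like cells of the IHG library had lower inflammatory (-0.28, 16 of 21 lower), interferon (-0.48, 21 of 22 lower) and immediate-early genes (-0.46, 15 of 16 lower), against a class median of 0.19. Haemoglobin RNA was also lower in this class (-2.51, 4 of 4 lower), and the macrophage gene C1qb was higher (7 and 159 UMIs, 3.26). The interferon-induced chemokine Cxcl10 had 269 UMIs in Ctrl and 73 in IHG (-3.12), and Ifi27l2a was at -1.49. The neutrophil attractant Cxcl2 was at -1.06, whereas the monocyte attractant Ccl2 was higher in IHG (454 and 2200 UMIs, 1.04). MHC class II genes, which present peptides to helper T cells, were at -0.34 (5 of 6 lower), and at 0.12 at clustering resolution 0.5. Endothelial-like cells had a higher activation list (0.46, 10 of 12 higher, against a class median of 0.20), with the adhesion genes Vwf (2 and 72 UMIs, 3.18, 1.28 to 6.26) and Sele (6 and 72 UMIs, 1.60), and lower proliferation genes (-1.49, 18 of 19 lower) beside lower haemoglobin RNA (-1.22, 4 of 4 lower). Their inflammatory list was at 0.08 (-0.44 to 0.15), and at -0.18 under median-of-ratios scaling, -0.02 without technical genes and -0.39 over members with at least 1 UMI. The matrix list was at 0.23 (-0.03 to 0.72), and at -0.03 under median-of-ratios scaling, and the interferon list was at 0.32 (20 of 23 higher).

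In fetal B-like cells the immediate-early list was lower in the IHG library in 16 of 16 members (-1.56, -1.66 to -1.46), with the growth-response transcription factors Fosb at -3.24, Fos at -2.88 and Egr1 at -2.86. The same list was at -1.57 in NK-like cells, where the haemoglobin list was at -5.16 and cluster 29 held 34 of 66 Ctrl and 6 of 46 IHG cells. B-like proliferation genes were at -0.18 (13 of 19 lower), where the histone-led cluster 11 held 443 of 1858 Ctrl and 109 of 847 IHG cells and cluster 3 held 466 and 383. Interferon genes were at -0.06. The hepatocyte list, a measure of free RNA outside hepatocytes, was at 1.00 in B-like and 0.96 in erythroid-like cells. In erythroid-like cells, the largest fetal class, the highest genes in IHG were Ndufa4l2 (1.85), a mitochondrial subunit induced by low oxygen, the glycolytic enzyme Pgam1 (1.53), Clint1 (1.43), Hist1h1b (1.15) and Ngp (1.04). Ngp is a neutrophil granule gene, and the granule list was at 0.99 (10 of 10 higher) in erythroid-like cells. The lowest included Polr2l (-0.92), the mitochondrial leucyl-tRNA synthetase Lars2 (-0.91), Hist1h2ap (-0.70) and Atp5md (-0.68). Erythroid oxidative phosphorylation genes were at -0.08 (0.31 when each library was clustered by itself) and proliferation genes at 0.09, against a class median of 0.29. The erythroid proliferation value was below 0 under median-of-ratios scaling (-0.20), without technical genes (-0.09) and with at least 500 genes per cell (-0.02). Proliferation genes of myeloid progenitor-like cells were at 0.31 (17 of 19 higher), and at -0.18 under median-of-ratios scaling. Cluster 14 held 64 of 125 Ctrl and 390 of 551 IHG cells of that class, and the granulocyte genes S100a8 (-1.51) and S100a9 (-1.08) were lower there in IHG.

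Fetal macrophage-like values rest on 6 Ctrl cells with 15594 UMIs. The inflammatory list was at -0.11 (-0.18 to 0.86, 11 of 23 higher) and at 0.57 under median-of-ratios scaling and 0.70 over members with at least 100 UMIs, against a class median of -0.75. Interleukin-1 beta (Il1b) had 0 UMIs in Ctrl and 1767 in IHG, at least 4.43-fold higher at the floor of 3 counts, and Il1a had 0 and 1073, at least 2.69-fold higher. Iron handling genes were at 0.54 (5 of 8 higher), with the ferritin heavy chain Fth1 at 1.30, and alternative activation and clearance genes at -0.45 (11 of 14 lower), which became 0.23 under median-of-ratios scaling. The mannose receptor Mrc1 was at -1.41. The lowest genes by size included the B-lineage genes Vpreb3 (16 and 35 UMIs, -5.93) and Cd79b (-3.65), so the 6 Ctrl cells carried B-lineage RNA. Neutrophil and red cell RNA was higher in the IHG cells of the class (S100a8 1.07, S100a9 0.88, Hbb-bs 1.65), and Il1b is also a leading gene of neutrophil-like cluster 17.

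The fourth comparison asks whether the makeup of the adult liver suspension differed between mothers. B-like cells were 53.0% of IHG cells (3439 of 6487) and 37.4% of Ctrl cells (1845 of 4937), a log2 ratio of 0.50. T-like cells were 25.3% and 31.3% (-0.31), and NK-like cells 11.7% and 13% (-0.16). Neutrophil-like cells were 1.63% (106) and 3.85% (190), a log2 ratio of -1.24 (-1.59 to -0.89). Endothelial-like cells, 0.401% and 0.790%, were at -0.98. Cholangiocyte-like cells, which line bile ducts, were 1.62% and 3.89% (-1.26), dendritic-like cells 1.43% and 3.42% (-1.26) and mesothelial-like cells 0.478% and 1.40% (-1.55). Macrophage-like cells were 0.755% (49) and 0.709% (35), a log2 ratio of 0.09 (-0.56 to 0.76), and held few UMIs of the macrophage complement genes C1qa (4 in Ctrl, 2 in IHG) and C1qb (0 and 5). Over all adult cells C1qa had 106 and 23 UMIs (-2.34), C1qb 175 and 32 (-2.58) and C1qc 108 and 8 (-3.89). In Ctrl 98 of the C1qa, 150 of the C1qb and 93 of the C1qc UMIs lay in monocyte-like cells, and in IHG 13, 12 and 3. At least 3 of 10 macrophage markers were found in 14 of 5245 Ctrl and 9 of 6851 IHG barcodes. Monocyte-like cells (1.80% and 1.74%, 0.05) and stellate/fibroblast-like cells (0.956% and 0.871%, 0.13) had close shares. Shares of a library depend on each other, so the higher B-like share by itself lowers the shares of T-like, NK-like and other cells. No other denominator was used for the adult shares, and dissociation and capture can set them too.

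No cluster of the adult libraries was hepatocyte-like, in the main setting or in any of the 9 settings that regrouped the cells. Single hepatocytes too few to form a cluster would lie in other clusters, so this sets no upper limit on their share. The acute-phase list in adult hepatocyte-like cells, planned as a main value, therefore has no value. Nearly all adult albumin UMIs lay in cholangiocyte-like cells (3413 of 3471 Alb UMIs in Ctrl and 1444 of 1483 in IHG). There, in a reading chosen after seeing the data, 8 of 13 positive acute-phase genes were higher in IHG, with a median of 0.02 (-0.21 to 0.09), of -0.01 without technical genes, -0.12 with thinned cells and -0.30 with cells weighted alike. The copper carrier ceruloplasmin (Cp) was at -0.22. Fgg was at 0.05, and at -0.31 with cells weighted alike and -0.66 with thinned cells. The siderophore binder Lcn2 (1057 and 434 UMIs, at 0.003) and C3 (0.02) were at -0.03 and -0.01 without technical genes and at -0.20 and -0.37 with cells weighted alike. Negative acute-phase genes were at 0.18 (6 of 7 higher), and at -0.26 when every cell had equal weight. The class joins cluster 11 (190 Ctrl and 82 IHG cells, median 7103.5 UMIs) with the shallow cluster 23 (2 and 23 cells, median 761 UMIs). Beside cholangiocyte markers, Ttr, Alb and Apoc1 were among the leading genes of cluster 11, and Hamp and Ahsg among those of cluster 23. Hepatocyte RNA is therefore not separated from the values of this class.

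The fifth comparison asks about inflammatory and other response genes in adult cells, whose class medians all lay within 0.1 of 0. Neutrophil-like cells of the IHG library had a higher inflammatory list (13 of 19 higher, 0.23, 0.15 to 0.42), with Il1b at 758 and 785 UMIs (0.97) and the NF-kB inhibitor Nfkbia at 621 and 596 (0.86), and a higher interferon list (0.49, 8 of 10 higher). Monocyte-like cells had a lower inflammatory list (-0.38, 13 of 21 lower), with the chemokine Ccl4 at -1.48 and Tnf at -1.33, lower MHC class II genes (-0.60, 5 of 6 lower, Cd74 at -0.66) and lower immediate-early genes (-0.61, 15 of 16 lower). C1qa (98 and 13 UMIs, -3.46) and C1qb (150 and 12, -4.19) were lower in the same class, so a macrophage subset among its Ctrl cells is not separated from these differences. Its interferon list was at -0.05 (-0.42 to 0.02), with Cxcl9 at 159 and 15 UMIs (-3.95, and 40.2% of UMIs from 1 cell). Endothelial-like inflammatory genes were at -0.74 (7 of 8 lower), but at 0.04 with a mitochondrial maximum of 10% and at 1.95 when each library was clustered by itself, and the activation list was at -0.21 (-0.47 to 0.24), but at 0.48 over members with at least 1 UMI, 0.25 with thinned cells and 0.16 with doublets kept.

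Interferon genes were higher in the IHG library in adult NK-like cells (16 of 19, 0.46, 0.30 to 0.63), with the RNA-binding effector Ifit1 at 1.04, and in T-like cells (15 of 21, 0.14, 0.07 to 0.30), with Isg15 at 0.59. In B-like cells they were at 0.04 (-0.15 to 0.22), and at -0.17 with thinned cells. Cytotoxic effector genes were at 0.16 (-0.01 to 0.31) in T-like cells, with granzyme K (Gzmk) at 1.05, and at 0.03 (-0.10 to 0.10) in NK-like cells, where they were at -0.01 without technical genes and -0.14 with thinned cells. Proliferation genes were lower in T-like (-0.41, 18 of 19 lower) and NK-like cells (-0.44, 8 of 10 lower), and the cycling T-like cluster 15 held 70 of 1544 Ctrl and 47 of 1638 IHG T-like cells. MHC class II genes were at 0.09 in B-like cells (6 of 7 higher, Cd74 at 0.29). Cluster 3, with Cd74, H2-Aa, H2-Eb1 and H2-Ab1 among its leading genes, held 164 of 1845 Ctrl and 646 of 3439 IHG B-like cells. In dendritic-like cells the MHC class II genes were at 0.06, and at -0.002 without technical genes and -0.06 with thinned cells. The stellate/fibroblast-like matrix list was at 0.23 (-0.07 to 0.38), and at -0.32 with thinned cells, with the elastic fibre gene Fbn1 at 1.47 and the collagen cross-linker Lox at -1.87.

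Adult macrophage-like cells came from 1 cluster with a median of 968 UMIs per cell and 7 detected markers. Their inflammatory list was at -0.17 (-0.51 to 0.30, 4 of 9 higher), with Cxcl2 at 0.92 (-0.04 to 1.97). Among genes with at least 100 CPM in 1 library and at least 50 UMIs, the highest in IHG were Atf4 (13 and 39 UMIs, 1.17), a transcription factor of the stress response, the ER chaperone Hspa5 (0.88), Dusp1 (0.81), Pabpc1 (0.78) and Kdm6b (0.76). The lowest were Sqstm1 (-1.34), Egr1 (-1.23), Id2 (-1.20), Btg2 (-0.996) and Eef2 (-0.80, -1.65 to 0.03). Gm42418, left out of this ranking, alone had 202836 CPM in Ctrl and 217657 in IHG. This class had no cells in either library in 4 of the 9 settings that regrouped the cells, and with each library clustered by itself it had 0 Ctrl and 48 IHG cells. In B-like cells, the largest adult class, the highest genes at the same minima included Hist1h2ap (1.14), AY036118 (0.85), Dnaja1 (0.54) and Wfdc17 (0.47). The lowest were the heat shock genes Hspa1a (-0.97) and Hspa1b (-0.95), Egr1 (-0.74), Plac8 (-0.72) and Tnfrsf13c (-0.54), the receptor for the B cell survival factor BAFF.

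**Figure D4:**
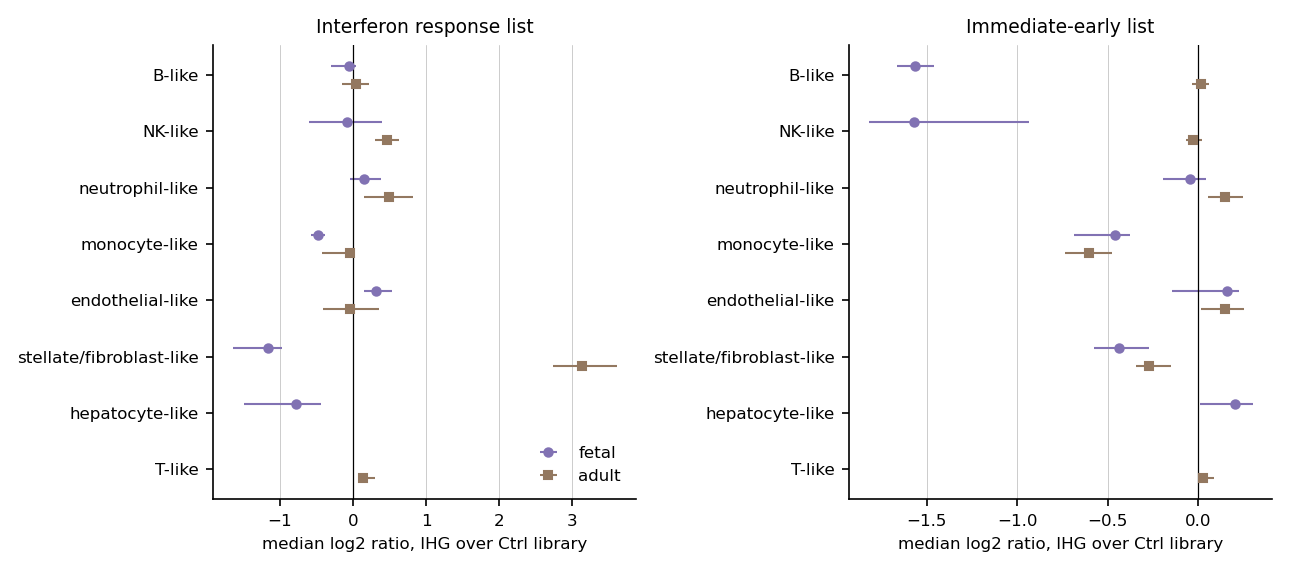
Median log2 ratio (IHG over Ctrl library) of the interferon response list (left) and the immediate-early list (right) by cell class, for fetal (circles) and adult (squares) libraries. Bars are 95% intervals for counting error, and the immediate-early list lies at -1.56 in fetal B-like cells.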

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

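The results below had opposite signs at the 2 ages, with intervals that exclude 0 at both, in 3 of 8 shares and 2 of 11 lists compared, and the differences between the ages were not tested. The tests of handling stress and of clusters 5, 17 and 7 taken singly were chosen only after the result was seen, and so was the stellate/fibroblast-like reading.

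B-like cells, the antibody lineage, had a log2 ratio of shares (IHG over Ctrl library) of -1.21 in the fetal and 0.50 in the adult libraries. Endothelial-like cells were at 1.67 and -0.98, and neutrophil-like cells at 1.00 and -1.24. Their adult values are not particular to them, since cholangiocyte-like (-1.26), dendritic-like (-1.26) and mesothelial-like cells (-1.55) were also lower there. Macrophage-like (0.09), monocyte-like (0.05) and stellate/fibroblast-like cells (0.13) were close to 0. The higher adult B-like share by itself lowers other shares. The inflammatory list in neutrophil-like cells was at -0.83 and 0.23. The interferon list in stellate/fibroblast-like cells was at -1.16 and 3.13.

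The fetal inflammatory list was lower in neutrophil-like cells of the IHG library, and since 2 of 3 clusters with at least 50 cells of each library had an upper bound under -0.2, a different mix of clusters cannot be told apart from a difference within clusters over the class. Within cluster 5 the median was -1.05 (and -1.07 in cluster 17), which argues against a mix of clusters there. A different mix of cells inside these clusters cannot be told apart, since their granule lists were also higher in IHG (0.51 and 0.67). Cluster 7, the main Ctrl cluster, was at 0.23, where mix of clusters may account for the class value. With all 5 clusters given the same weights in both libraries the median was -0.50 (17 of 21 genes lower), and with equal weights -0.65 (18 of 21). Handling stress in the Ctrl library cannot be told apart either, since the immediate-early list was at -0.0451 (-0.20 to 0.04) with members in both directions, at -0.33 in cluster 17, -0.32 in cluster 8, -0.07 in cluster 10, -0.04 in cluster 5 and 0.16 in cluster 7. It was at -1.56 in B-like, -1.57 in NK-like, -0.46 in monocyte-like, 0.16 in endothelial-like and 0.24 in erythroid-like cells, and the mothers' hyperglycemia stays open, untested.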

How the results depend on the processing

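Of 3440 alternative values over 282 results, 3337 had the sign of the reported value, 103 the opposite sign, and 44 of these, in 28 results, reversed a value whose interval excluded 0. Alternatives without haemoglobin-rich cells, with the same cells thinned and over cells outside erythroid-like and unnamed clusters were chosen after seeing the data. For the values below the cause was not tested. No paired analysis was possible because the groups share only a replicate number.

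The fetal acute-phase list in hepatocyte-like cells (0.64) stayed above 0 in every alternative run. It was at 0.44 under median-of-ratios scaling, 0.41 without technical genes, 0.33 with cells weighted alike and 0.53 over members with at least 100 UMIs. With all cells thinned it was at 0.20, with each library clustered by itself at 0.83, without haemoglobin-rich cells at 0.18 and with the same cells thinned at 0.26. Above 0 is not above the class, however. Without haemoglobin-rich cells the list's interval (0.06 to 0.36) held the class median of 0.12, and the negative acute-phase list was at 0.28. The fetal neutrophil-like share (1.00) was at 0.89 with a mitochondrial maximum of 50% and 0.65 over cells outside erythroid-like and unnamed clusters. Other results moved beyond their interval without reversal in 668 of 3362 alternatives.

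Under median-of-ratios scaling the hepatocyte-like immediate-early list was at -0.0007 (0.20 as reported), macrophage-like alternative activation at 0.23 (-0.45), erythroid-like proliferation at -0.20 (0.09), myeloid progenitor-like proliferation at -0.18 (0.31) and hepatocyte-like C3 at -0.0276 (0.17). Without technical genes the immediate-early list was at -0.033, hepatocyte-like oxidative phosphorylation at -0.0196 (0.21), erythroid-like proliferation at -0.0942 and C3 at -0.0597. With cells weighted alike Acly was at 0.0875 (-0.75), the adult cholangiocyte-like negative acute-phase list at -0.26 (0.18) and Ttr there at -0.19 (0.19).

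Thinned to 1000 UMIs, the fetal NK-like share was at 0.27 (-0.60), hepatocyte-like Cdk1 at 1.06 (-2.25), monocyte-like H2-Ab1 at 0.24 (-1.47) and Cd74 at 0.51 (-0.66), endothelial-like Nfkbiz at -1.07 (0.62) and adult NK-like Ifit3 at -0.0795 (1.47). With a mitochondrial maximum of 10% the fetal unnamed share was at 0.0471 (-0.25) and the adult endothelial-like inflammatory list at 0.041 (-0.74), and with 50% the NK-like share was at 0.26. With at least 500 genes the NK-like share was at 0.20, erythroid-like proliferation at -0.0173 and adult endothelial-like Ccl4 at 1.38 (-1.94), and with at least 200 genes Ccl4 was at 1.16. With doublets kept the unnamed share was at 0.63, adult neutrophil-like Cxcl10 at -0.56 (1.92) and Ccl4 at 1.499. At resolution 0.5 monocyte-like MHC class II was at 0.12 (-0.34), Cd74 at 0.15 and Ccl4 at 1.29.

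With each library clustered by itself the plasmacytoid share was at -0.26 (0.80), erythroid-like oxidative phosphorylation at 0.31 (-0.08), the adult endothelial-like inflammatory list at 1.95, Ccl4 at 7.37 and Klf4 at -0.13 (1.05). Without haemoglobin-rich cells complement was at -0.31 (0.33), bile acid genes at -0.24 (0.39), oxidative phosphorylation at -0.0266, C3 at -0.33 and Ube2c at 0.10 (-2.57). With the same cells thinned Gys2 was at -0.56 (1.64), Xbp1 at -0.14 (0.77) and Cdk1 at 0.61.

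The adult hepatocyte-like class gave no value in any setting. The adult macrophage-like class had no cells in 4 settings, and with each library clustered by itself it had 0 Ctrl and 48 IHG cells, so its share had no value in 5 settings and its list in 6. The fetal macrophage-like list had no value in 2 settings, and the share had none with each library clustered by itself, where Ctrl had 0 such cells. The fetal plasmacytoid share had no value in 5 settings. Fetal monocyte-like and megakaryocyte-like shares had none with each library clustered by itself, and the adult monocyte-like share had none with thinned cells. Some other lists and genes also lacked a value in some settings.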

Other observations

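Interferon-induced genes, which block viral replication and amplify their own signal, set the adult stellate/fibroblast-like cells of the libraries apart. Cells of this class lay down matrix, and the adult cluster was led by the fibroblast genes Gsn, Dpt and Dcn. The list was higher in the IHG library in 21 of 21 measured genes, with a median log2 ratio of 3.13 (2.74 to 3.61), over 43 Ctrl and 62 IHG cells. Ifit3, which binds signalling partners of viral RNA sensors, had 6 and 266 UMIs (4.57, 3.43 to 6.03). Usp18, a feedback inhibitor of interferon signalling, had 0 and 30 UMIs, at least 5.35-fold higher at the floor of 3 counts per class sum. The median over cells of the list's CPM was 3173 in Ctrl and 17066 in IHG, and 50 of 62 IHG cells lay above the Ctrl median. The chemokine Ccl2 had 23 and 410 UMIs (3.25).

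In fetal stellate/fibroblast-like cells (17 Ctrl and 23 IHG) the same list was lower in the IHG library in 12 of 12 genes (-1.16, -1.65 to -0.97), with Isg15 at 129 and 47 UMIs (-2.71) and Ifit3 at 88 and 23 (-3.19). RNA of other cell types also differed in these cells, with the neutrophil gene S100a9 at 138 and 2544 UMIs (2.95) and Hba-a1 at -1.05. Both readings were picked out after all 574 had been seen. The 3 tests of fetal macrophage-like cells and the comparison of the positive with the negative acute-phase list were chosen only after the result was seen.

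Fetal macrophage-like cells were few in the Ctrl library. Barcode filters used here are argued against, since among all barcodes 8 of 8500 in Ctrl and 472 of 8739 in IHG had at least 3 of 10 macrophage markers, a ratio of 0.0174 (0.00748 to 0.0346). Burst macrophages whose RNA stayed in the suspension are argued against by C1q UMIs in B-like cells, 8 in Ctrl and 148 in IHG (ratio of their share of UMIs 0.0336, 0.0142 to 0.0679). Earlier bursting cannot be told apart, since RNA freed before the low-speed spin could have been removed. Lower recovery of all non-blood cells alike is argued against by endothelial-like, stellate-like and hepatocyte-like cells together, at 0.61 (0.33 to 0.89) against 5.80 (4.66 to 7.25). A loss of macrophages alone in dissociation was not tested, and the mothers' hyperglycemia stays open, untested.

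The fetal acute-phase list was higher in hepatocyte-like cells of the IHG library. It was not higher there alone. Within neutrophil-like clusters the same list was at 0.60 (cluster 5), 0.77 (7), 0.39 (8), 0.74 (10) and 0.79 (17), and its members Orm1 and Lcn2 are leading genes of cluster 10. The hepatocyte list, a measure of free RNA, was also higher in B-like, erythroid-like and neutrophil-like cells of the IHG library. A share of free RNA in the hepatocyte-like difference was not tested. Erythroid RNA in Ctrl cells may account for most of the hepatocyte-like difference, since the median was 0.18 without cells of over 10% haemoglobin UMIs. More hepatocyte RNA of several kinds may also do so, since the positive list lay -0.0436 (-0.32 to 0.12) from the negative list. Not every list of the class went the same way. Without haemoglobin-rich cells fatty acid synthesis genes were at -0.72 and cholesterol synthesis genes at -0.39, while glucose metabolism genes were at 0.41 and urea cycle genes at 0.44. The haemoglobin list was still at -1.10 in those cells, so RNA of other cells is not separated from these values. Deeper cells in the IHG library cannot be told apart, with a median of 0.26 (0.06 to 0.54, 11 of 16 higher) after thinning the same cells, an interval too wide to decide. The mothers' hyperglycemia stays open, untested.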
